A study of Mus musculus with 20 samples.

How the data were processed

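Tail DNA of 10 mice (1 sire, 1 dam, 8 offspring) was hybridised on 20 Agilent oligonucleotide arrays against DNA of 1 reference male, per the labels. Each animal was labelled with Cy3 on 1 array and with Cy5 on the other. The labels gave the group and number of each animal, and the dye of each channel. They did not give the sex of the offspring. Later steps of the study, higher-density arrays and quantitative copy number assays, are not analysed here.

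Per the file headers, the arrays were read with Agilent Feature Extraction. The deposited intensity values used were the processed red (Cy5) and green (Cy3) signals, which per the file headers were background-subtracted with spatial detrending and scaled by a linear dye normalization, with no lowess term. The deposited log10 ratio of red over green was the logarithm of the ratio of these signals in all but 7 to 65 spots per array, at a tolerance of 0.001. Probe coordinates were those of the NCBI37 (mm9) design named in the headers. The deposited series table held log2 values. Set against the scanner ratios, its columns held the reference over the animal on every array, with correlations across probes of at least 0.992 where the animal was in Cy3 and between -0.9988 and -0.9859 where it was in Cy5. Its column medians lay between -0.0045 and 0.0138, so it was on the scale and nearly the centring of the scanner ratios. The step that made it is not given in the sources used here. No column of these files lacked a sample.

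From the 973116 spots per array, 6745 control spots and the outlier spots flagged by the scanner software were left out, repeated spots of a probe were averaged, and 36 probes on unplaced sequence were left out. The log2 ratio of animal over reference was centred on the autosomal median of each array, and the 2 orientations of an animal were averaged. No loess or quantile step was applied, since copy number can shift many probes of an interval 1 way. No spot was saturated, and 937162 probes were well above background in both channels of all arrays. Median net signals ranged from 82.0 in green on 1 array of the dam to 366.5 in red on 1 array of offspring 6. Before dye bias was removed, the 2 orientations of an animal correlated negatively across probes, which are not independent replicates (r from -0.38 to -0.18), because a dye bias enters them with opposite sign. After each probe's median dye bias was removed, r was 0.004 to 0.19. Arrays of different animals in 1 orientation correlated at 0.25 to 0.51.

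Copy number intervals were found in each animal by a score, the sum of probe log2 ratios over their noise SD divided by the square root of the number of probes. An interval needed a score of at least 6 in size, at least 3 probes, an absolute mean of at least 0.25, and both orientations of the same sign with at least 50% of that mean limit. Overlapping calls of a sign were merged into regions. An animal carried a region if it was called in it or had a mean of at least 0.2 in size and a score of at least 3. Regions were shared by all animals, carried by a parent but not by all, or offspring-only. False calls were estimated from dye-difference data: the 2 orientations of an animal subtracted and divided by 2, with each probe's median over animals removed. These data hold 1 value per probe and animal, so the requirement per orientation could not remove calls from them. In simulated intervals added to these data, the scan found 97.8% of 3-probe gains of 0.5, 37.1% of 3-probe gains of 0.3 and 100.0% of 50-probe gains of 0.3. The requirement per orientation was not in force there either, and the share found with it was not measured. These choices were made before the data were examined, and the 30-probe minimum afterwards. Regions were to be named by a fixed rule: every offspring-only region if there were 10 or fewer and otherwise the 10 of highest score, with the 10 highest-scoring shared and 10 highest-scoring parent-carried regions. Region scores were taken in the direction of the region, a correction made after a first ranking.

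Offspring and parents were compared by an exact two-sided permutation test of calls per animal and by limma (lmFit and eBayes on 1 mean log2 ratio per probe and animal, Benjamini-Hochberg threshold 0.05). On simulated normal noise of equal spread over 950622 probes, limma found 99 of 100 probes shifted by 1 and 44 of 100 shifted by 0.5, with 6 other probes called. The p-values measure the spread between animals of a single family. The 2 parents were scanned on 1 day and the offspring on 4 others.

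Each result was also computed, as set out before the data were examined, with other score, probe and mean limits, with no requirement per orientation, with normexp (offset 50), loess (span 0.3), subtraction of a running median along the chromosome, probes well above background, the series table, a looser carrier rule, limma with an intensity trend, and each animal left out in turn. Normexp used median spot signals, because the files used here have no mean signal. The running median stood in for a GC correction, since no mm9 sequence was used here. Chosen after seeing the data were the 30-probe minimum, at least 3 probes of an interval past 0.25, subtraction of dye bias, weights per animal, scan day as a random block, and leaving out animals for the region counts. The planned test of overlap with gene lists (the chromosome 19 segment around Ide, substrain deletions, chemosensory receptors, defensins, natural killer receptors, histocompatibility genes, urinary proteins, antigen receptors, zinc finger clusters, Y-linked genes and DNA damage genes) and the naming of genes were not run. The files used here pair no probe with a gene, and the gene table at hand was on another assembly. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.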

Results

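Genomic DNA from the tails of 10 C57BL/6-type mice of 1 family was compared with DNA of a reference male from the same colony by array comparative genomic hybridisation, in which animal and reference DNA carry different fluorescent dyes and compete for the same probes. The family held 1 sire, 1 dam and 8 offspring. Each animal was hybridised on 2 arrays with the dyes exchanged, and the 2 arrays counted as 1 replicate of that animal. The series title describes copy number in the progeny of male mice that received gamma rays at 1 mGy per day for 400 days, whereas the design text calls the sire and the dam non-irradiated. No exposure was therefore assigned to any animal, and no comparison of irradiated with unirradiated mice was made. Each array held 950713 probes after repeated spots were averaged, of which 950622 were autosomal, 68 lay on the X and 23 on the Y chromosome. The median spacing of autosomal probes was 2053 bp. The derivative log ratio spread, a measure of probe-to-probe noise, had a median of 0.176 over the 20 arrays. The dam's array with the animal in Cy5 was the noisiest, at 0.227, and an array of offspring 6 the quietest, at 0.146. The number of arrays per animal limits the precision of every value.

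The X and Y chromosomes gave a copy difference known from the labels, since the sire and the reference were male and the dam female. The X log2 ratio of the dam over the reference was 0.97 ± 0.061 and that of the sire was -0.04 ± 0.044 (SD of the 2 dye orientations of 1 animal). Dam minus sire was 1.01, near the value of 1 for 2 copies against 1. The sex of the offspring was not labelled, so their values are given singly. Offspring 5, 6, 7 and 8 had X log2 ratios of 1.00, 0.88, 0.93 and 0.97. Offspring 1, 2, 3 and 4 had X log2 ratios of 0.00, 0.04, 0.09 and -0.02. The Y log2 ratio was -3.36 in the dam, which corresponds to 9.75% of the reference signal. Among the offspring with X log2 ratios of 0.88 or more, the Y signal was 5.72% of the reference in offspring 5, 21.1% in offspring 6, 6.47% in offspring 7 and 11.4% in offspring 8. The sire had a Y log2 ratio of -0.30 ± 0.257, and offspring 1 to 4 lay between -0.04 and 0.02. With normexp background correction, dam minus sire on the X chromosome shrank to 0.63, and the Y log2 ratios became -0.28 in the dam and -0.46 in offspring 6, so that the dam had the higher Y value.

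**Figure D1:**
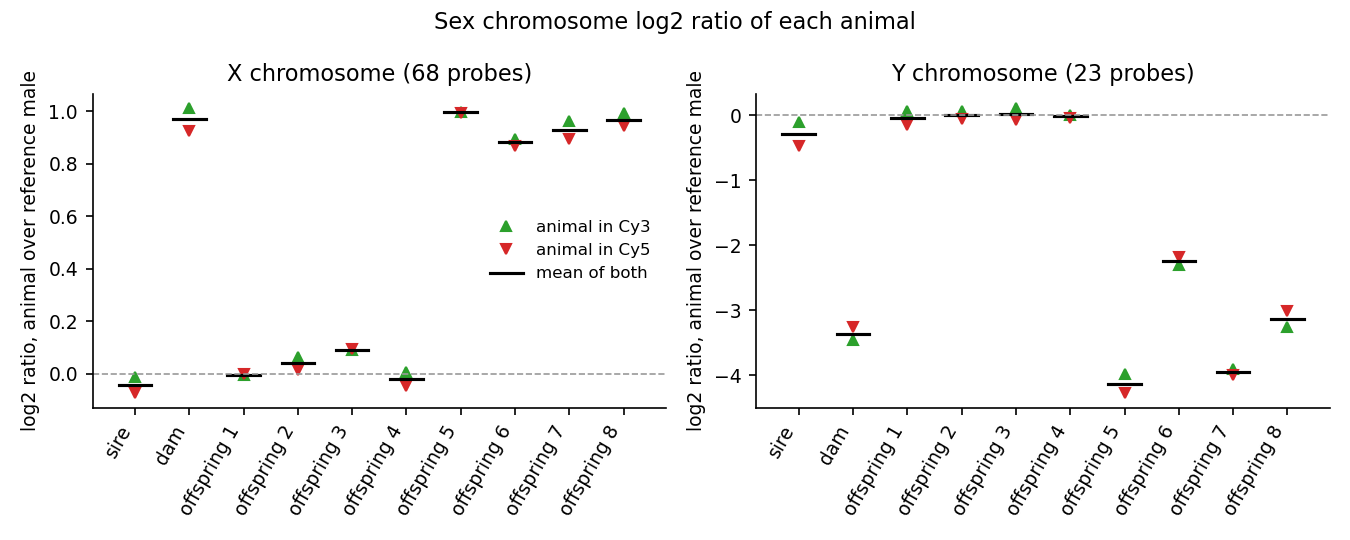
Log2 ratio of each animal over the reference male on the X chromosome (left, median of 68 probes) and the Y chromosome (right, median of 23 probes). Triangles are the 2 dye orientations and bars their mean; the dam and offspring 5 to 8 lie between 0.88 and 1.00 on the X chromosome, and offspring 6 has a Y log2 ratio of -2.25.

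The autosomes were screened for intervals gained or lost against the reference, the purpose of the primary screen. No whole-chromosome change was seen: the largest absolute chromosome median in any animal was 0.012. Under the rule set before the data were examined, 1758 calls were made in the 10 animals and merged into 1557 regions, 786 gains and 771 losses. Most were very short, with 1617 calls of 3 to 4 probes. The dye-difference data, in which the 2 orientations of an animal were subtracted so that copy number cancels, gave 2603 calls of that length and 2708 in all. There were 100 calls of 5 to 9 probes against 103 in the dye-difference data. In 955 of the 1557 regions, a single probe passed the limit of 0.25 in the animal of highest score. The requirement per orientation could remove calls from the animals but not from the dye-difference data, so calls were not counted on equal terms. Summed over the 10 animals, calls of 3 to 9 probes did not exceed those in the dye-difference data. Offspring 8 was an exception, with 417 calls against 367 at 3 to 4 probes and 24 against 1 at 5 to 9 probes. Calls of 10 to 29 probes numbered 17 against 2. Those of 30 or more numbered 24 against 0, and this stricter length, chosen after the data were seen, was used for the regions described first. The 24 long calls formed 6 regions, 3 gains and 3 losses, which are described here by their coordinates in the NCBI37 (mm9) mouse assembly. The array files used here name no genes, so the genes in these regions are not given. Each region's values are means over its probes, and the standard error from probe noise is given where an animal's value is compared.

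Offspring-only regions, present in offspring but not in either parent, were the aim of the family design. A gain on chromosome 4, from 101110482 to 101270535 (160.1 kb, 74 probes), was found in offspring 6 and offspring 7 with identical first and last probes. The mean log2 ratio was 0.52 in offspring 6 and 0.57 in offspring 7, against 0.58 for 3 copies instead of 2. The other 8 animals lay between -0.02 and 0.01. The sire had 0.00 ± 0.014 and the dam 0.01 ± 0.0158 (SE from probe noise), so the upper 95% limit corresponds to a gain in at most 3.8% of the sire's and 5.2% of the dam's tail cells, probe noise alone being counted. Over non-overlapping 74-probe windows outside the called regions, the largest absolute mean was 0.071 in offspring 6 and 0.056 in offspring 7. Called intervals of every animal were left out beforehand, so large means could hardly remain. The dye orientations of these 2 animals ranged from 0.503 to 0.583.

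**Figure D2:**
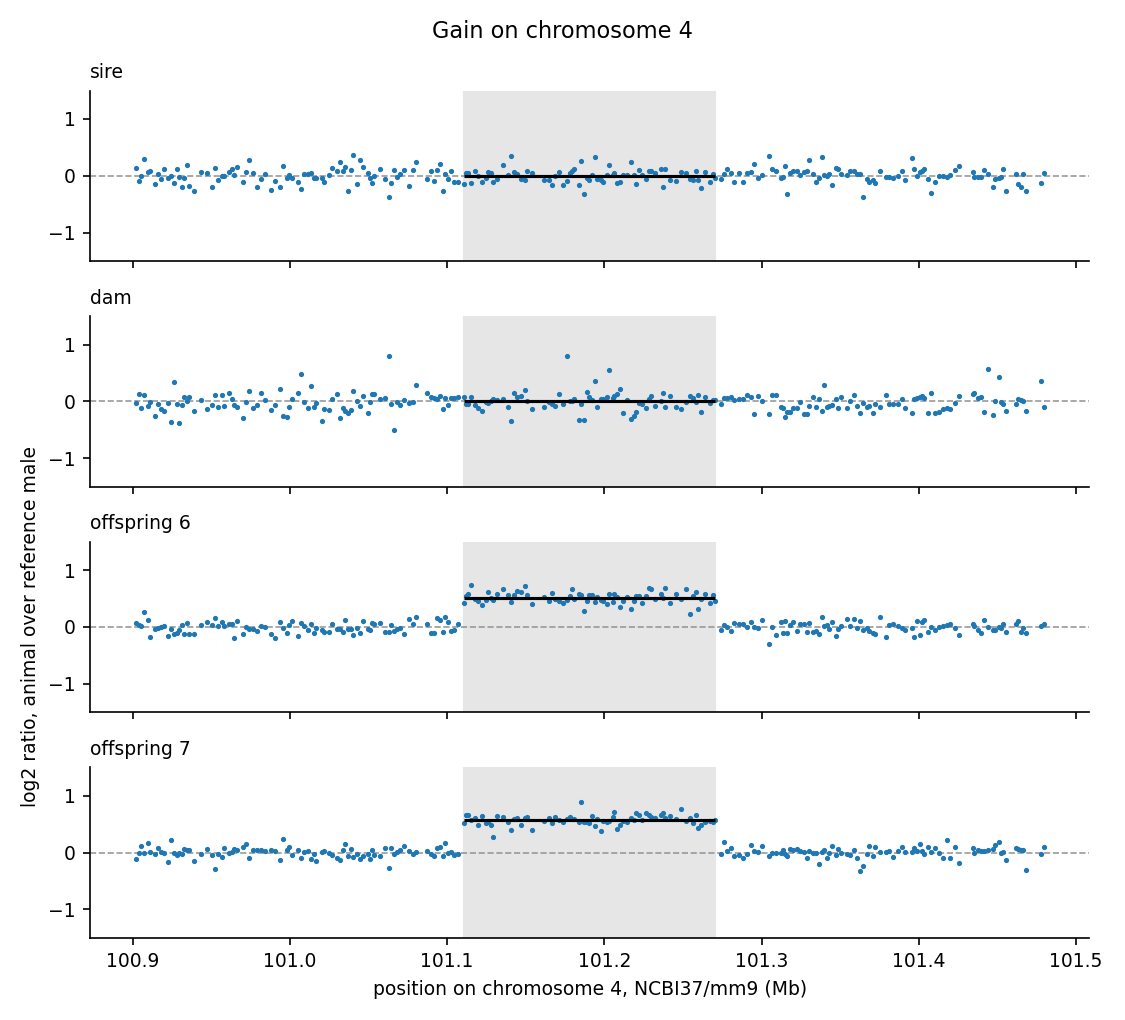
Log2 ratio over the reference of each probe against position on chromosome 4 (Mb, mm9) in the sire, the dam, offspring 6 and offspring 7. The shaded interval is the called gain and the black lines are its means, which lie at 0.00, 0.01, 0.52 and 0.57.

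A loss on chromosome 7, from 75325727 to 75442178 (116.5 kb, 57 probes), was found in offspring 6 alone. Its mean log2 ratio was -0.84, with -0.865 and -0.813 in the 2 dye orientations, and the other 9 animals lay between -0.049 and 0.014. The loss of 1 of 2 copies in every cell would give -1. Over non-overlapping 57-probe windows outside the called regions, the largest absolute mean in offspring 6 was 0.071. As on chromosome 4, called intervals were left out beforehand, so large means could hardly remain.

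**Figure D3:**
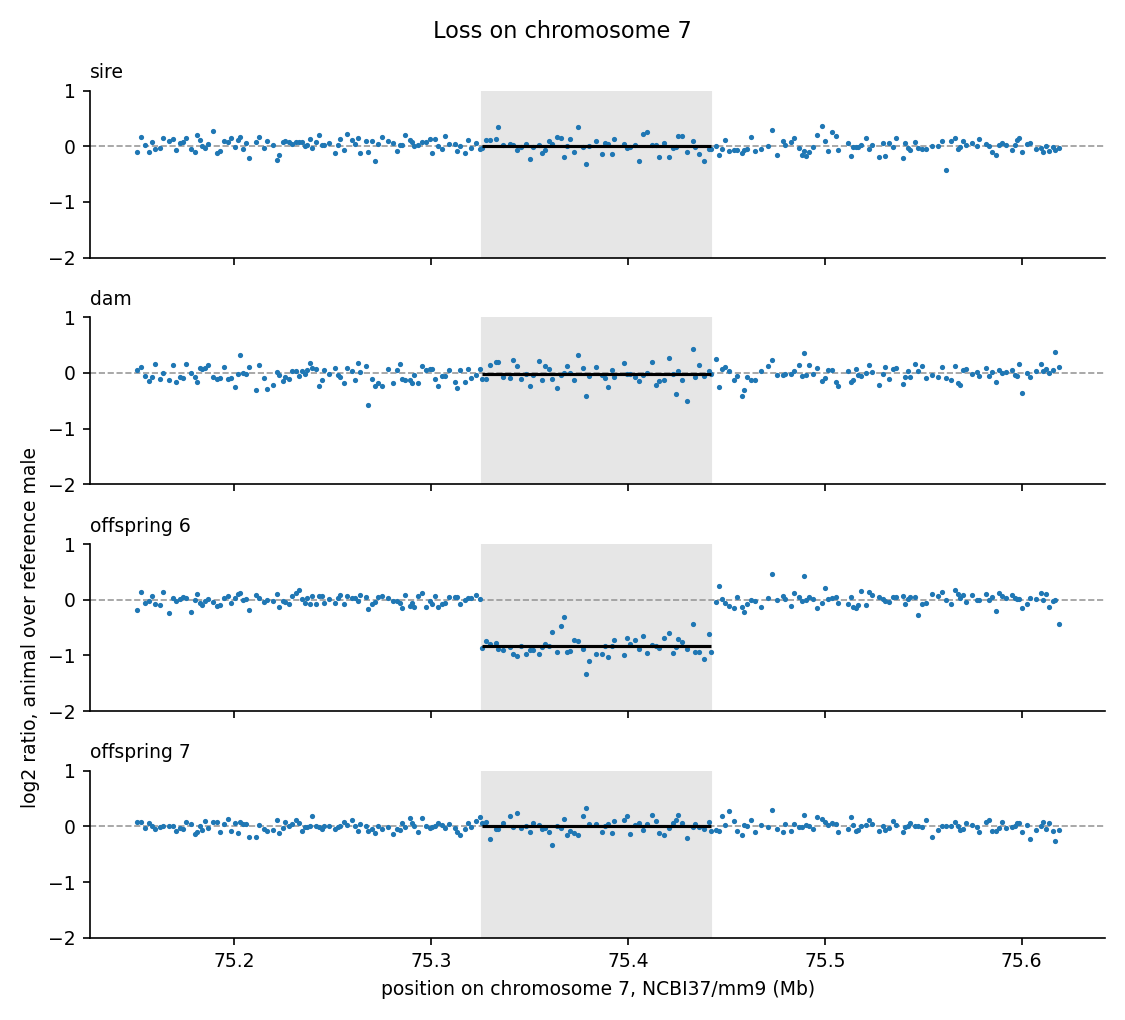
Log2 ratio over the reference of each probe against position on chromosome 7 (Mb, mm9) in the sire, the dam, offspring 6 and offspring 7. The shaded interval is the called loss and the black lines are its means, which reach -0.84 in offspring 6 alone.

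The third offspring-only region was a shallow loss on chromosome 6, from 41072975 to 41495198 (422.2 kb, 129 probes). It was called in offspring 3, at a mean log2 ratio of -0.25, and the other 9 animals lay between -0.03 and 0.02. This size corresponds to 16.0% fewer copies than in the reference. Over non-overlapping 129-probe windows outside the called regions, the largest absolute mean in offspring 3 was 0.078. Here too, called intervals were left out beforehand, so large means could hardly remain.

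Regions carried by a parent but not by all animals numbered 578 under the planned rule and 2 at 30 or more probes, both carried by the dam. A gain on chromosome 14, from 26694134 to 26953407 (259.3 kb, 66 probes), was carried by the dam and 4 of 8 offspring, numbers 2, 3, 4 and 8. Its log2 ratio ranged from 0.30 to 0.32 over these 5 animals and from -0.03 to 0.01 over the other 5. A gain on chromosome 8, from 102125282 to 102253497 (128.2 kb, 46 probes), was carried by the dam and offspring 5, 6, 7 and 8. Its log2 ratio ranged from 0.25 to 0.29 in these 5 animals and from -0.02 to 0.01 in the other 5. Both gains lay below the 0.58 that 3 copies instead of 2 would give. The carriers of the chromosome 8 gain were the same 5 animals whose X log2 ratios were 0.88 or more. No region of 30 or more probes was carried by the sire and not by the dam.

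The other named parent-carried regions had 3 to 14 probes. A loss of 3 probes on chromosome 3, from 25417435 to 25432738, had log2 ratios from -1.67 to -1.43 in the dam and offspring 5 to 8, and from -0.19 to 0.06 in the other animals. Losses on chromosome 6 (from 104238274), chromosome 3 (from 132546474) and chromosome 16 (from 40849337) and a gain on chromosome 10 (from 22555501) were carried by the same 5 animals. The chromosome 10 gain was called in offspring 8 alone, and the chromosome 16 loss was not called in the dam. The other carriers there met the limits on mean and score without a call. A gain of 14 probes on chromosome 11, from 3066271 to 3098381, was carried by the dam and offspring 5, at 0.24 to 0.32. The other 8 animals ranged from -0.14 to 0.19, so carriers and others were not clearly set apart. A gain on chromosome 13 (from 95703166) was carried by 8 animals, the sire and dam included, and a 4-probe gain on chromosome 11 (from 76357341) by offspring 1, 3, 7 and 8 and, by its mean alone, the sire. The sire was not called there, and its 2 dye orientations were -0.121 and 0.656. In offspring 7, the animal of highest score, this gain changed sign with normexp.

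The remaining named offspring-only regions held 3 to 6 probes. At that length the dye-difference data, without the requirement per orientation, gave as many calls over all animals. They were losses on chromosome 16 (from 36137719), chromosome 6 (from 77475781) and chromosome 1 (from 194797899), and gains on chromosome 14 (from 53954543 and from 52008939), chromosome 17 (from 29715081) and chromosome 15 (from 82097455). Of the 15 named regions of fewer than 30 probes, 9 had a single probe past 0.25 in the animal of highest score. The gain from 53954543 on chromosome 14 lost its sign in offspring 5 when only probes well above background were used, at -0.37 against 0.61. It ended at 53987490 and so lay within the chromosome 14 loss shared by all animals, described below. Offspring 4 was also called in it but had a mean of 0.099 over the region, against 0.147 in the sire.

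Only 1 region was shared by all 10 animals. This loss on chromosome 14 ran from 53385238 to 54804468 (1419.2 kb, 295 probes), and a change of the common reference male would appear in every animal in this way. The 9 animals other than offspring 3 were called over 53 to 104 probes, with means from -0.342 to -0.283 over their own intervals. Offspring 3 was called over all 295 probes at -0.34. Over the whole region, the other 9 animals lay between -0.144 and -0.076, so most of their loss was in its first part. Probe density was low in the middle of the region.

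**Figure D4:**
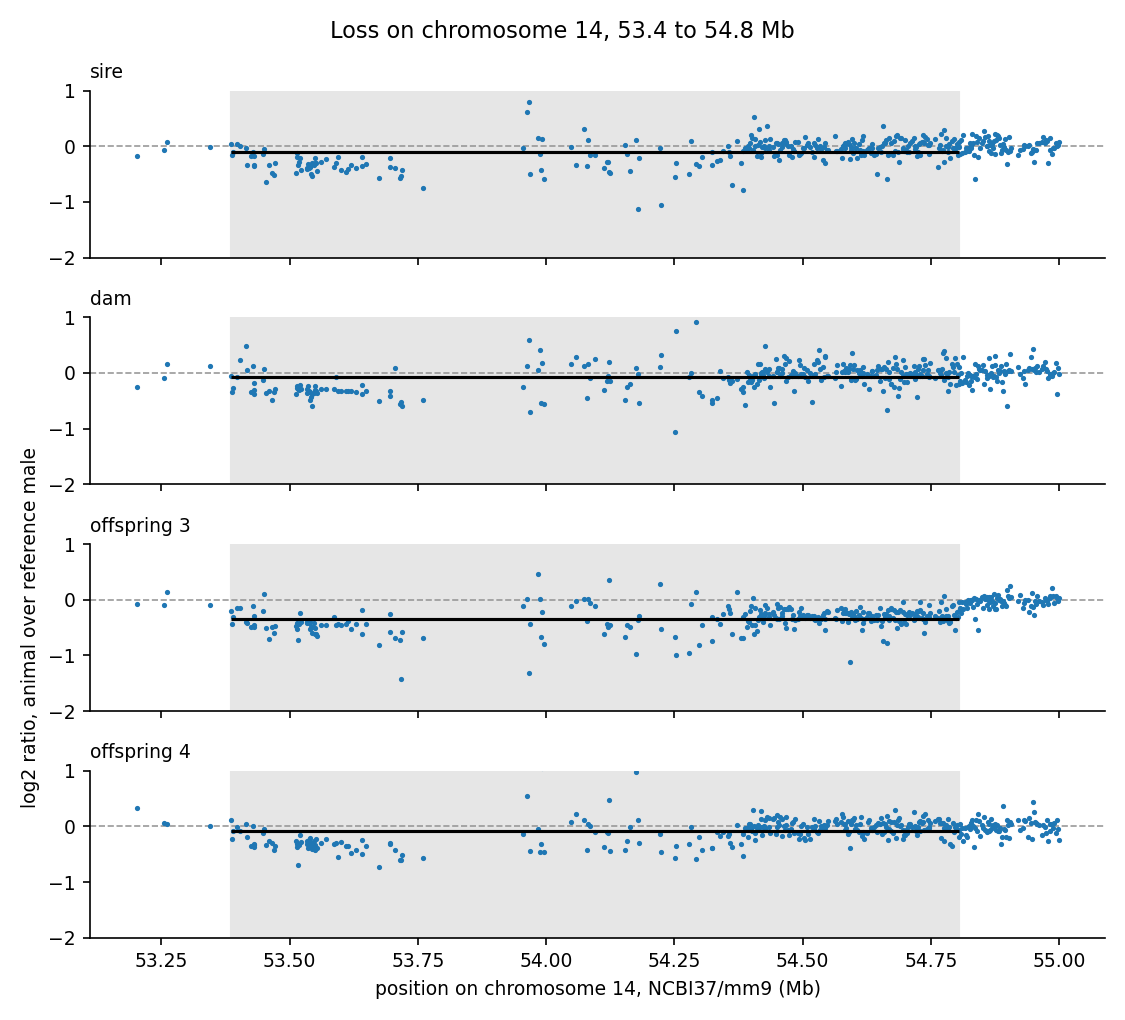
Log2 ratio over the reference of each probe against position on chromosome 14 (Mb, mm9) in the sire, the dam, offspring 3 and offspring 4. The shaded interval is the region and black lines are its means; the loss of offspring 3 continues to the right edge at a mean of -0.34, and 2 probe values fall outside the plotted range.

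**Figure D5:**
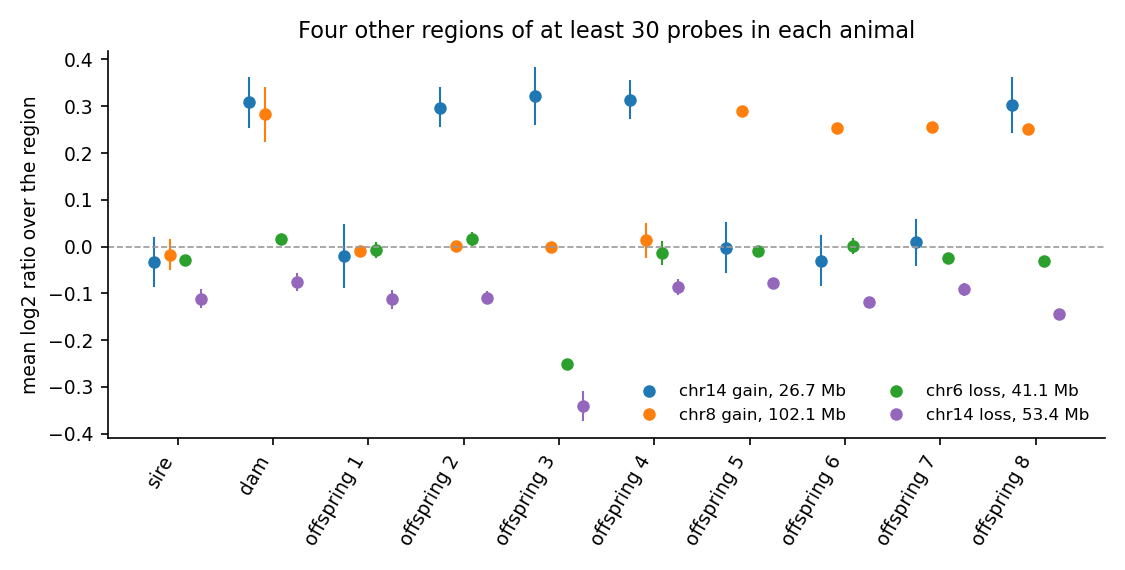
Mean log2 ratio of each animal over the gains on chromosomes 14 and 8 and the losses on chromosomes 6 and 14. Points are means of the dye orientations and vertical lines join the 2 orientations; the dam and 4 offspring carry each gain, and offspring 3 is lowest for both losses, at -0.25 and -0.34.

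Progeny and parents were then compared directly. The mean number of calls per animal was 170.1 in the 8 offspring and 198.5 in the 2 parents, a difference of -28.4 that did not pass an exact permutation test (two-sided p = 0.756, 45 splits). The smallest p this design allows is 0.022. Offspring 8 had 446 calls, against 72 to 215 in the other offspring. The difference passed the test with a limit of 0.5 on the mean log2 ratio, at -61.0 (exact permutation p = 0.044), with means of 24.5 calls in the offspring and 85.5 in the parents. The parents also had the highest probe noise of the 10 animals, with an SD of 0.120 in the sire and 0.136 in the dam, against 0.09 to 0.114 in the offspring. The difference changed sign with a score limit of 8, with probes well above background and with normexp, which gave 46.8 more calls per animal in the offspring.

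Probe by probe, 12 of 950086 autosomal probes differed between offspring and parents (limma, Benjamini-Hochberg adjusted p below 0.05), 3 higher and 9 lower in the offspring. The lowest adjusted p, 0.00048 in limma, belonged to a probe at 16099621 on chromosome 15, with a mean log2 ratio of -0.05 in the offspring and -1.04 in the parents. The 12 probes lay on 10 chromosomes, and the closest 2 on a chromosome were 4.13 Mb apart, so none formed an interval. The same limma fit called 25 probes in the dye-difference data, which hold no copy number signal. The count fell to 0 with probes well above background on all arrays, and rose to 3086 without the sire, 95 without the dam and 60 with scan day as a random block. The sire and dam were scanned on 1 day and the offspring on 4 other days, so scan day and generation could not be told apart for the parents.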

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

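The tests of explanations in this part were all chosen after the patterns were seen. Among 27 sets of 8 offspring values, 9 held a value far from the other 7, and chance gives about 1 in 20 such sets. The named regions were chosen by score, which favours a single far animal.

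Offspring 6 had a chromosome 7 log2 ratio of -0.839, against -0.049 to 0.014 in the other offspring, and shared the chromosome 4 gain with offspring 7. Dye bias or noise of single arrays is argued against by the dye orientations, whose difference divided by 2 was at most 0.026 over the 3 calls, while an artefact common to both arrays of an animal stays open. Male DNA mixed into the sample of offspring 6, at the 11% to 16.3% that its Y signal would correspond to, is argued against as the source of the chromosome 7 loss, because a share of 16.3% lacking the interval altogether would give -0.26, but it stays open as the reason why the values fall short of -1 and 0.58. This share rests on the median of 23 Y probes. Their single values in offspring 6 ranged from -3.597 to 1.154, so single probes would give very different shares. Male DNA would add its share to every Y probe, yet some probes lay at -3.597 to -3.318, which corresponds to less than 11%. The range of 11% to 16.3%, and the values computed from it, may therefore be too high a share. A share of 11% to 16.3% would give 0.88 to 0.92 on X, 0.50 to 0.53 on chromosome 4 and -0.85 to -0.78 on chromosome 7. Offspring 6 had 0.88, 0.52 and -0.84 there. Its chromosome 4 gain was 0.06 ± 0.013 (SE from 74 probes), or 10.4%, below that of offspring 7. Carriers other than offspring 6 differed by 13.1% over the chromosome 8 gain and by 7.8% over the chromosome 14 gain, so this comparison cannot decide. A carrier of the chromosome 14 gain (offspring 2, 3 or 4) as the source would give 0.04 to 0.05 there, where offspring 6 had -0.03. With normexp, the Y log2 ratio of offspring 6 (-0.46) fell below that of the dam (-0.28, from -3.36), with 0.96 on X against 0.61 in the dam. Since normexp moved the dam's own X and Y values far from those of a female, this comparison cannot bear on male DNA. Offspring 6 then had -0.73 on chromosome 7 and a chromosome 4 difference of 0.035 ± 0.015. Whether the labelled sire is the sire cannot be told apart, because 0 regions of 30 or more probes were carried by the sire and not by the dam, and germ cells of the parents were not measured.

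The chromosome 8 gain and the chromosome 3 loss were carried by the dam and offspring 5 to 8, the animals with X log2 ratios of 0.88 or more. In all, 11 regions (2 gains, 9 losses) had exactly these carriers, although the dam was not itself called in those on chromosomes 1, 10 and 16. The most for any other of the 70 patterns of the dam and 4 offspring was 1. In 8 of the 11, a single probe passed the limit of 0.25 in the animal of highest score. This is consistent with autosomal probes that also bind X or Y sequence. A chromosome 3 deletion passed on by the dam is argued against by the dam's log2 ratio of -1.52 ± 0.0787 (SE from probe noise), beyond the loss of 1 of 2 copies, while an offspring reached 0.06. No biological explanation was tested for the other 10 regions. The chromosome 8 gain, at 0.25 to 0.29 in its carriers, lay below the 0.58 that 3 copies instead of 2 would give. Its inheritance stays open.

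Offspring 3 was lowest for both the chromosome 14 loss, at -0.341 against -0.144 to -0.078 in the other offspring, and the chromosome 6 loss, at -0.252 against -0.03 to 0.016. A deletion of 1 copy in every cell is argued against on chromosome 6 by a log2 ratio of -0.25 ± 0.0092 (SE from probe noise). In the mouse, chromosomes 6 and 14 carry T cell receptor genes, which are cut and joined in T cells, so lymphocytes in the tail sample were considered as a source. Relative to the median of the other 9 animals, the chromosome 14 loss of offspring 3 was deeper over its last 99 probes than over its first 98, with a difference of -0.11 ± 0.033 (SE from probes), but the same difference ranged from -0.09 to 0.05 in the other 9 animals; on chromosome 6 it was -0.11 ± 0.03, against -0.05 to 0.08, which is 1.9 SE beyond the lowest of them. Rearranged receptor DNA and another deletion in part of the cells thus cannot be told apart, and the intervals were not placed on genes here.

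Offspring 8 had 446 calls, against 72 to 215 in the other offspring. Offspring 4 had -0.962 over a 4-probe loss on chromosome 6 (from 77475781), and offspring 1 had -0.891 over a 3-probe loss on chromosome 1 (from 194797899). Offspring 5 had 0.606 over a 6-probe gain on chromosome 14 (from 53954543), which lies within the loss shared by all animals. Offspring 8 had 0.69 over a 3-probe gain on chromosome 17 (from 29715081), with 0.242 in Cy3 and 1.138 in Cy5. Offspring 3 had 0.783 over a 3-probe gain on chromosome 15 (from 82097455). In each of these gains of offspring 8 and offspring 3, only 1 probe passed 0.25, so the means do not describe the whole interval.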

How the results depend on the processing

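The alternatives with a 30-probe minimum, supported probes, dye bias subtracted, weights per animal, scan day and region counts without an animal were chosen after the data were seen. Of the 6 regions of 30 or more probes, 3 remained in number with a mean of at least 0.5, with 0 carried by a parent but not by all. The other alternatives run at that length kept all 4 counts within 1.5 times, apart from leaving out animals. Leaving out each animal gave 5 to 6 such regions, 2 to 5 offspring-only and 0 to 2 carried by a parent but not by all, with 1 shared throughout. Without the dam, the 2 gains the dam carries became offspring-only. Without offspring 6 or without offspring 3, each the only carrier of a loss, 2 offspring-only regions were left.

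Counts under the planned 3-probe rule moved widely. Regions in all, carried by a parent but not by all, and offspring-only numbered 316, 138 and 177 at a score of 8, 4160, 1449 and 2710 at a score of 5, 626, 205 and 420 at 5 probes, and 303, 214 and 87 at a mean of 0.5, where 2 were shared. They numbered 393, 30 and 362 with normexp, 534, 95 and 438 with probes well above background, 138, 74 and 63 with at least 3 probes past 0.25, and 6, 2 and 3 at 30 probes. Leaving out each animal gave 1164 to 1518 regions, 275 to 572 parent-carried (275 without the dam, 317 without the sire) and 633 to 1099 offspring-only (633 without offspring 8), with 1 shared. The cause was not tested.

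Offspring minus parents in calls per animal changed sign at a score of 8 (2.2), with normexp (46.8), with probes well above background (44.2) and at 30 probes (0.5). It passed the exact permutation test at a mean of 0.5 (-61.0) and with at least 3 probes past 0.25 (-22.8, p = 0.022, the smallest the design allows). Leaving out each animal gave -67.8 to -7.9. The X log2 ratio of dam minus sire was 0.63 with normexp and 0.97 with loess. The 12 probes of limma became 0 with normexp, where 51962 had an unadjusted p below 0.05, and 0 with probes well above background (84474), 2 with weights per animal, 60 with scan day as a random block, and 3 to 3086 when an animal was left out (3086 without the sire, 95 without the dam, 47 without offspring 4, 3 without offspring 6, 7 without offspring 7). With 1 parent left, that animal was assumed to vary like the offspring.

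Of 30 alternative values of the 6 regions of 30 or more probes, 22 moved by less than the spread of the dye orientations, 8 moved by more and 0 changed sign. Of 75 values of the shorter named regions, 3 changed sign: the gain on chromosome 11 (from 76357341) in offspring 7 with normexp (-0.01), and the gain on chromosome 14 (from 53954543) in offspring 5 with normexp (-0.1) and with probes well above background (-0.37). The gene list overlap and its Fisher alternative were not run. No paired analysis was possible because the parents are 1 sire and 1 dam and share no more than 1 number with the offspring. Spots not well above background, whose ratios are least precise, numbered from 268 on an array of offspring 6 to 9845 on an array of the dam.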
